A study of Mus musculus with 10 samples.

How the data were processed

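Total RNA was extracted with TRIzol from pre-B acute lymphoblastic leukaemia tumours taken from untreated mice and processed at once, per the labels' protocols. It was converted to cDNA from an oligo-dT primer with a T7 promoter and transcribed in vitro with biotinylated nucleotides, also per the labels' protocols, so signals come mainly from the 3' parts of polyadenylated transcripts. The deposited table holds 1 log2 value per probe set and array, made with affy and RMA per the submitters' processing notes. RMA corrects background, equalises the distributions of probe intensities and summarises the probes of a set. The versions of both tools, the probe-set definition and any filter are not given in the sources used here. The log2 scale was inferred from RMA and from the range of the deposited values, which had medians from 5.12 to 5.23, and whether a further centring was applied is unknown. RMA compresses differences near background and uses the other arrays of a study to set each value, so a level can shift with the set of arrays.

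The 10 arrays were assigned to tumours by sample, and all belonged to 1 group. Replicate numbers came from the labels. The most probe-set values shared exactly by a pair of arrays was 36 of 45101, so no array was treated as a duplicate. No slide, scan or processing batch is given in the labels, so none could be tested.

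Probe sets were named from the platform annotation. Of 45101 probe sets 34958 named 1 gene, 932 named several and were not used, and 9211 were unlisted and are unnamed here. Symbols were checked through Entrez identifiers against a table of mouse genes on assembly GRCm38.p6, which held 96.8% of them, and 0 symbols changed. That table was otherwise used only for which genes lie on 1 chromosome and in what order, and no coordinates are printed because the labels name no genome build. Each of 18194 genes was represented by its probe set with the highest mean, and probe sets of a gene can disagree. Apart from this choice, the detection level and the selection of genes by mean, no probe set's level was read as more or less abundant than another's. Kras, Cd19 and Trp53, along with Hras, Raf1, Mapk1, Mapk3, Lyn, Ighd and Sell among the listed genes, had no probe set assigned to them alone and were not analysed here.

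The gene lists, tests, alternatives and rule for naming genes were fixed before the data were examined, except where stated. A gene counted as detected when its mean lay above 6.57, the 95th percentile of the means of 44 measured genes, of 50 listed, from tissues other than blood. Of these off-tissue genes 3 were detected. The 21 fixed lists held 389 genes, of which 351 were measured, and covered B lineage stages, Ras and MAPK genes, cell cycle and p53 genes, proliferation, Myc, JAK-STAT, Bcl2 family, other cell types, interferon, stress, sex-linked and off-tissue genes. Named genes were those of the genotype, the 20 most variable detected genes outside immunoglobulin, sex-linked and predicted genes (3 were passed over), the pairs of members with the largest and the smallest SD in each list, up to 5 genes per direction in each fit, and the 5 least variable genes in the upper part of the detected means. Other genes named in the text, such as the remaining list members and those of the closing section, were chosen after their values were seen.

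A list score was the mean over detected members of the log2 value minus the gene mean. Median SD and mean pairwise correlation of a list were set against 10000 random lists matched in 20 bins of mean expression, for lists with at least 4 detected members. Pairs of scores were tested with two-sided permutation tests of 100000 resamples, which can give no p below 1e-05, and adjusted by Benjamini-Hochberg over 11 pairs, since the Kras pair of the 12 planned could not be computed. No pair was withheld for separate clusters of tumours. Genes were regressed on 4 scores with limma (lmFit, eBayes with trend) at a Benjamini-Hochberg adjusted p of 0.05, leaving out members of the list that made the score, and each count was set beside those of 100 random orderings of the tumours. The other-cell covariate was the mean of 4 list scores (T and NK, macrophage, erythroid and megakaryocyte, stromal), because the granulocyte list had 0 detected members. Tumours were not grouped by any measured outcome.

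The alternatives were averaging the probe sets of a gene, leaving out probe sets that may cross-hybridise, centring arrays on the median, quantile normalization, other detection levels or none, z-score and median list scores, the scaled median absolute deviation, the other-cell covariate, limma without trend, leaving out the 2 tumours farthest from the median score, and leaving out each tumour. Leaving out tumours 4 and 7, a detection level on the highest tumour, and removing the stress, other-cell, T and NK or granulocyte score from every gene before the MAPK output list was correlated were added after the data were seen.

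The steps were tested on simulated data over 7324 genes. Their noise was drawn independently for each gene, whereas genes on these arrays moved together, so the rates below may not carry over to the real data. With 100 genes planted per size, limma recovered 76 of 100 at 0.5 log2 and 94 of 100 at 1 log2 per score SD for the MAPK output fit, 79 and 92 for proliferation, 75 and 95 for mature B and 79 and 100 for Cdkn2a, with 7.61%, 3.39%, 2.86% and 5.79% false calls. Unstructured lists exceeded the 95th percentile in 3.5% of cases for spread and 4.0% for correlation, and planted lists in 86.0% and 100% of 50 cases. Of 500 unrelated pairs 6.2% had a permutation p under 0.05. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1.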

Results

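Gene expression was measured on 1-colour Affymetrix arrays in 10 pre-B acute lymphoblastic leukaemia tumours, a malignancy of B cell precursors. The tumours arose in C57BL/6 mice that carried a Cre recombinase expressed from the Cd19 locus, active in B lineage cells, 1 Kras allele with the activating G12D change, and 1 altered allele of Ink4a/Arf, written L in the labels and read here as conditional, the locus that encodes the tumour suppressors p16Ink4a and p19Arf. All 10 formed 1 untreated group with no normal or wild-type sample, so the results give the level of each gene, its spread between tumours and which genes moved together. Tumours are named by the replicate numbers 1 to 10 of the labels, which give no anatomical site and do not state that each tumour came from a separate mouse, so p-values measure only the spread between these samples, which may be partly technical. The medians of the arrays over 45101 probe sets were 5.19, 5.17, 5.19, 5.23, 5.19, 5.15, 5.16, 5.12, 5.14 and 5.19 on the log2 scale for tumours 1 to 10. Pearson correlations between arrays, computed across genes, which are not independent replicates, ran from 0.845 (tumours 4 and 9) to 0.957 (tumours 1 and 10). The number of arrays limits the precision.

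Of 18194 genes, 7324 had a mean above the detection level of 6.57, and most of these varied little between tumours. Scp2, Eef1a1, Rpl4, Actb and Copb2, which serve lipid transfer, translation, the cytoskeleton and vesicle transport, had the smallest SDs among the more highly expressed genes, from 0.0356 (Scp2) to 0.0517 (Copb2). The median SD was 0.248, and 155 genes (2.12%) had an SD above 1. The most variable were Bpifa2 and Chia1, which encode secreted proteins of saliva and other epithelial fluids. Bpifa2 reached 14.34 in tumour 4 and 14.41 in tumour 7. It stood at 7.95 in tumour 8, 7.05 in tumour 6 and 6.72 in tumour 5, and below the detection level in the others. Chia1 reached 13.16 and 13.60 in tumours 4 and 7 against at most 6.22. Scgb1b27, a secretoglobin, stood at 14.64 in tumour 4 and 8.98 in tumour 7 and was at most 6.45 in the others, while Wfdc12 stood at 11.39 and 9.32 in the same tumours. Igf2, a fetal growth factor, was 11.94 in tumour 1 and 11.75 in tumour 10 and at most 6.15 in the others. Enpep, a peptidase found on B cell precursors, ranged from 3.70 in tumour 1 to 11.61 in tumour 6, and Glycam1, a ligand of L-selectin on the venules of lymph nodes, from 4.60 in tumour 6 to 10.87 in tumour 5. The others among the 20 most variable genes were Myl4, Scin, Cxcl13, Ccr1, Cdh17, Ly6d, Fabp4, Tnfrsf19, Epb41l4b, Cybb, Tnni2, Col3a1 and Il1r2, with SDs from 1.63 (Il1r2) to 2.27 (Myl4). The count of genes with an SD above 1 was 103 when the probe sets of a gene were averaged and 295 with no detection filter.

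**Figure D1:**
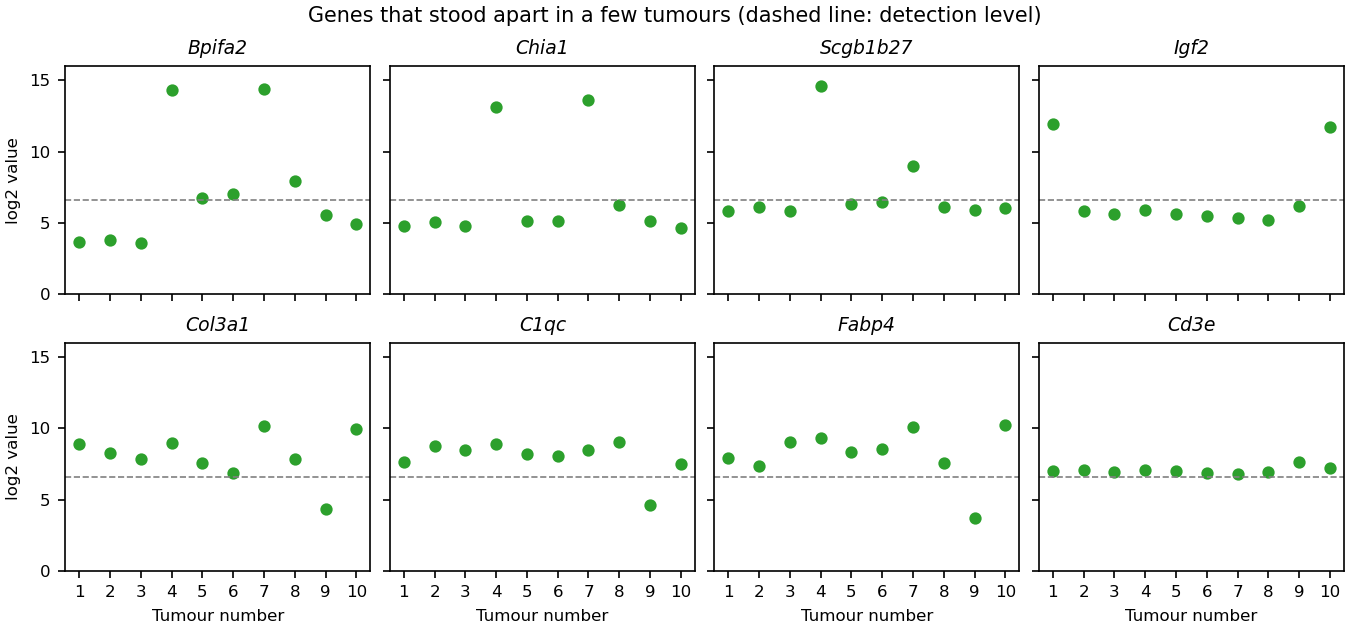
Log2 values (vertical axes) of 8 genes in each of the 10 tumours (horizontal axes), 1 point per tumour, with the detection level of 6.57 as a dashed line. Bpifa2 and Chia1 lay above 13 in tumours 4 and 7, Igf2 above 11 in tumours 1 and 10, and Col3a1, C1qc and Fabp4 below 5 in tumour 9.

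The first question was how far the tumours kept the identity of B cell precursors. All 16 measured pan-B genes were detected, 15 of them in every tumour. Cd79a, a signalling chain of the pre-B cell receptor, stood at 12.82 ± 0.26 (mean ± SD, n = 10), Cd79b at 12.05 ± 0.34, Ebf1 at 9.76 ± 0.42 and Pax5 at 7.19 ± 0.34, the last pair being transcription factors that commit cells to the B lineage. Of 15 B progenitor genes 13 were detected, among them the surrogate light chain genes Vpreb1 (12.55 ± 0.45), Igll1 (11.31 ± 0.57) and Vpreb3 (12.05 ± 0.26). Other members of both lists differed widely between tumours. Rag1, a subunit of the recombinase of immunoglobulin genes, ran from 6.43 in tumour 2 to 10.69 in tumour 7, and Lef1 from 6.94 in tumour 4 to 9.30 in tumour 6. The pan-B gene Blk, a kinase of the B cell receptor pathway, ran from 5.59 in tumour 1 to 10.58 in tumour 4. The pan-B gene Cd24a, a surface protein of B precursors, ran from 8.79 in tumour 1 to 12.81 in tumour 2. Cd19, whose locus drives Cre, and Lyn had no probe set assigned to them alone and are not reported.

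Genes of mature B cells were the most uneven of the lineage groups. All 19 measured members lay above the detection level in at least 1 tumour, but 9 did so in every tumour, and the median SD of the 12 detected members was 0.960. Ms4a1, which encodes CD20, ran from 4.97 in tumour 6 to 9.47 in tumour 9. The MHC class II gene H2-Eb1 ran from 7.50 in tumour 3 to 11.66 in tumour 9, and Cd74, the class II invariant chain, from 9.41 in tumour 4 to 13.09 in tumour 1, with a mean of 11.56 ± 1.16 (n = 10). The score of the list, the mean deviation of its detected members from their gene means, was lowest in tumour 4 (-1.06) and highest in tumour 9 (0.94). Tumour 4 carried salivary transcripts and tumour 9 had the lowest stromal score (-2.23). Tumour 4 was also lowest for the B progenitor (-0.45), Ras component (-0.27), cell cycle inhibitor (-0.37) and proliferation (-0.50) scores. The lowest pan-B, MAPK output, p53 target and Myc scores were in other tumours. Whether the share of tumour cells in a sample contributed to these scores was not tested. Among 10 measured germinal centre and plasma cell genes 7 were detected. Mzb1, a chaperone of immunoglobulin assembly, was even (11.96 ± 0.27), while Jchain ran from 6.02 in tumour 1 to 9.09 in tumour 9 and Sdc1 from 5.77 in tumour 10 to 8.05 in tumour 5.

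**Figure D2:**
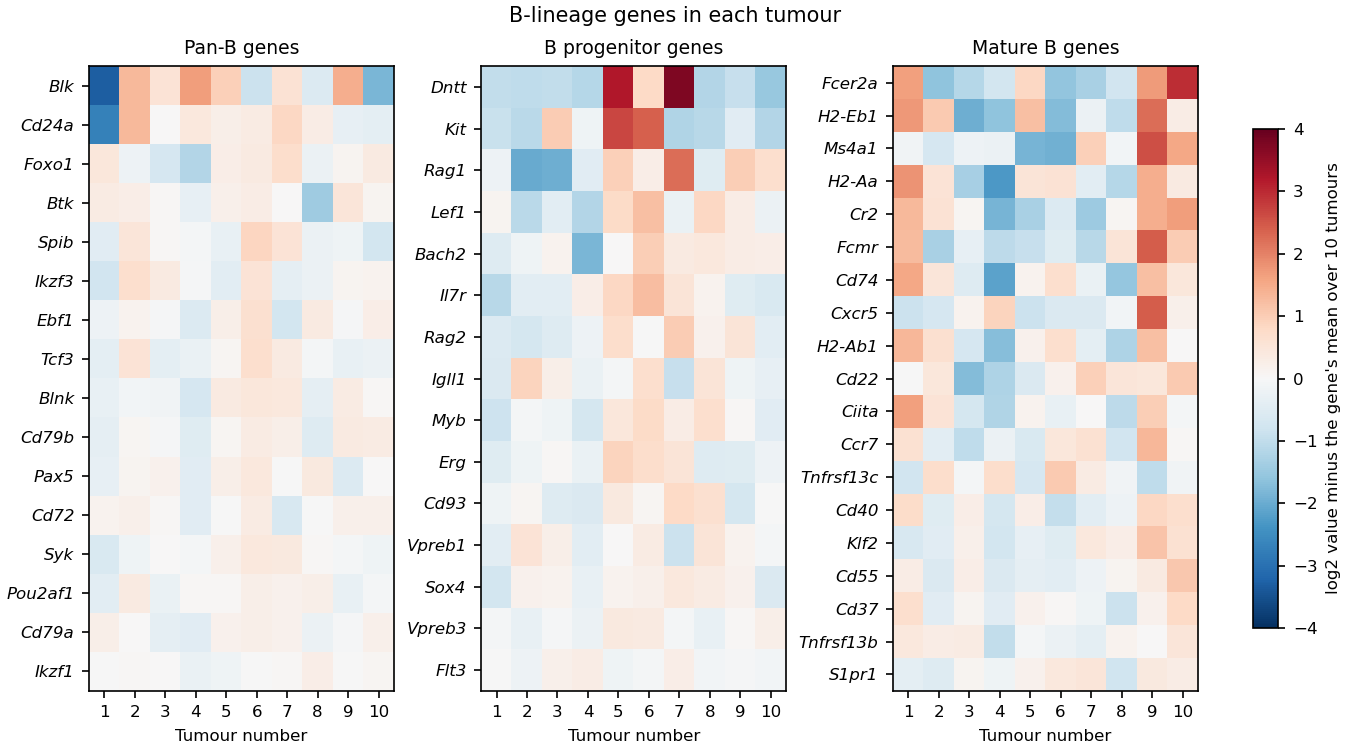
Heat maps of the pan-B, B progenitor and mature B genes above the detection level in at least 1 tumour (16, 15 and 19 genes, vertical axes) in tumours 1 to 10 (horizontal axes), coloured by log2 value minus the gene's mean over the 10 tumours. Blk was lowest in tumour 1 (5.59), Dntt highest in tumours 5 (9.36) and 7 (9.90), and H2-Eb1 highest in tumour 9 (11.66).

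The genotype involves Ink4a/Arf and Kras. Cdkn2a, the gene of Ink4a/Arf, had a log2 value of 4.49 ± 0.45 (n = 10), from 3.99 in tumour 8 to 5.49 in tumour 9, and its neighbour Cdkn2b one of 4.62 ± 0.73, with 6.50 in tumour 1 and at most 4.83 in the others. Neither gene reached the detection level of 6.57 in any tumour, so their differences between tumours may be mostly background. Where the Cdkn2a probe set lies relative to any conditional segment is not given in the sources used here, so its level checks nothing about deletion. Kras and Trp53 had no probe set assigned to them alone and are not reported. Among 17 measured cell cycle inhibitors and RB pathway genes 14 were detected, and Cdk6 (8.71 in tumour 10 to 11.37 in tumour 8) and Ccnd2 (5.77 in tumour 2 to 8.90 in tumour 1), which drive the exit from G1 phase, had the largest SDs. Of 17 measured p53 targets 8 were detected, with Btg2 from 8.38 in tumour 4 to 10.41 in tumour 9 and the cell cycle inhibitor Cdkn1a from 7.33 in tumour 9 to 8.93 in tumour 6.

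The detected components of the Ras pathway were even between tumours, while genes induced by its output were not. Of 21 listed components Kras, Hras, Raf1, Mapk1 and Mapk3 had no probe set assigned to them alone and are not reported. Among 12 detected components the adaptor Grb2 (9.45 ± 0.11, n = 10) and the kinase Araf (7.67 ± 0.12) varied least, and Rasgrp2, an exchange factor, varied most (9.55 ± 0.44). Of 18 measured MAPK output genes 9 were detected. The feedback phosphatase Dusp6 stood at 10.45 ± 0.40 and the feedback inhibitor Spred2 at 9.08 ± 0.19. Ccnd1, which encodes cyclin D1, ran from 6.87 in tumour 2 to 11.35 in tumour 1, and Phlda1 from 5.33 in tumour 2 to 9.95 in tumour 1. The MAPK output score was 0.88 in tumour 1, 0.67 in tumour 10 and 0.48 in tumour 5, and lowest in tumours 4 (-0.55) and 2 (-0.80).

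Proliferation genes were expressed in every tumour, and their levels moved together. All 25 detected members of 26 measured lay above the detection level in each tumour. Rrm2, a subunit of ribonucleotide reductase, ran from 9.22 in tumour 4 to 11.23 in tumour 8, Ccna2, which encodes cyclin A2, from 9.25 to 10.98 in the same tumours, and Mki67 stood at 10.57 ± 0.43 (n = 10). The proliferation score was lowest in tumour 4 (-0.50) and highest in tumour 8 (0.57). These tumours also had the lowest and the highest median deviation over all detected genes, -0.146 and 0.123. Of 18 Myc and ribosome biogenesis genes 17 were detected, with Myc at 8.57 ± 0.48 and the nucleolar protein gene Nop56 at 8.99 ± 0.44. In the JAK-STAT group all 12 genes were detected, and the cytokine-induced feedback gene Socs2 varied most, from 5.90 in tumour 2 to 9.84 in tumour 3, while Stat5b varied least (7.67 ± 0.10). In the Bcl2 family Bmf (6.27 in tumour 2 to 8.61 in tumour 6) and Bcl2l1 (6.72 in tumour 7 to 8.94 in tumour 6) varied most among 7 detected members.

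Genes listed as markers of other cells were present and differed by tumour. Whether tumour cells express any of them was not tested. Stromal and endothelial genes were low in tumour 9, where the collagen gene Col3a1 stood at 4.36 against 6.89 to 10.16 in the others and Cxcl13, a chemokine of lymphoid stroma, at 5.42 against 6.10 to 11.27. Complement genes of macrophages followed the same tumour, with C1qc at 4.65 there and 7.49 to 9.03 elsewhere. The score of the 12 detected stromal genes was -2.23 in tumour 9 and at least -0.58 in the others, and that of the 8 detected macrophage genes was -1.55 there and at least -0.33 in the others. Among T and NK cell genes 5 of 20 measured were detected. Cd2 (6.68 in tumour 8 to 9.63 in tumour 9) and Cd5 (4.88 in tumour 6 to 8.56 in tumour 1) had the largest SDs. Cd3e (7.07 ± 0.24, n = 10) and Zap70 (7.85 ± 0.12) had the smallest. None of 13 measured granulocyte genes had a mean above the detection level, although 6 exceeded it in some tumour. Of 15 measured erythroid and megakaryocyte genes 4 were detected. Car2 stood at 10.96 ± 1.10, and Epor (7.00 ± 0.18), Itga2b (6.72 ± 0.13) and Pf4 (6.63 ± 0.91) lay near the detection level. Interferon-induced genes, 7 of 17 detected, were highest in tumour 4 (score 0.93), where Rtp4 reached 8.91 and Oas2 7.76. Of 12 stress and immediate-early genes 8 were detected, with Jun from 4.73 in tumour 2 to 8.95 in tumour 9.

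**Figure D3:**
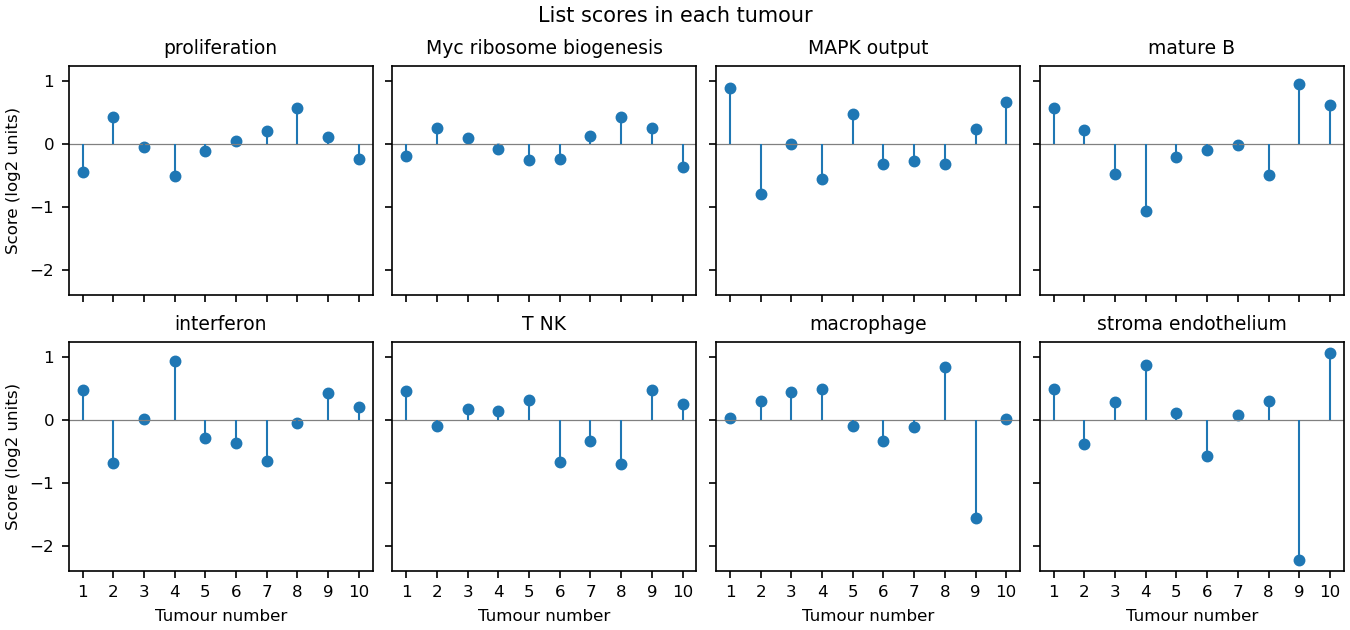
Scores of 8 gene lists (vertical axes, mean log2 deviation of the detected members from their gene means) in tumours 1 to 10 (horizontal axes), 1 point per tumour joined to 0 by a line. Tumour 9 had the lowest stromal (-2.23) and macrophage (-1.55) scores, tumour 8 the highest proliferation score (0.57) and tumour 1 the highest MAPK output score (0.88).

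Lists were then compared with 10000 random lists of detected genes of equal size and matched mean. The proliferation genes had the highest mean pairwise correlation (r = 0.758, with 0.10 as the median of matched lists), followed by stromal (0.731), Myc and ribosome biogenesis (0.686), macrophage (0.648), interferon (0.545), MAPK output (0.406), stress (0.348), mature B (0.277), cell cycle inhibitor (0.265), B progenitor (0.244) and pan-B genes (0.238). These 11 of 18 lists lay above the 95th percentile of matched lists, with the MAPK output list at 99.6. With each array centred on its median 8 lists did, the pan-B, B progenitor and mature B lists no longer, and without probe sets that may cross-hybridise 9 did, the mature B and stress lists no longer. Median SDs lay above the 95th percentile in 14 lists, highest for stromal (0.990), mature B (0.960) and macrophage genes (0.629), and in 10 lists with the scaled median absolute deviation, which left out the germinal centre and plasma cell, p53 target, Bcl2 family and erythroid lists. The Myc (90.7), stress (92.3), T and NK (52.9) and Ras component lists (18.7) did not reach it. Germinal centre and plasma cell genes (-0.0363), Bcl2 family genes (-0.0537), erythroid genes (-0.0209) and p53 targets (0.0276) had correlations below the median of matched lists, while JAK-STAT (0.113), T and NK (0.121) and Ras component genes (0.192) lay above that median but not above the 95th percentile. Because genes are not replicates, the percentiles describe these 10 arrays. Granulocyte genes, with 0 detected members, and sex-linked genes, with 1, received no percentile.

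**Figure D4:**
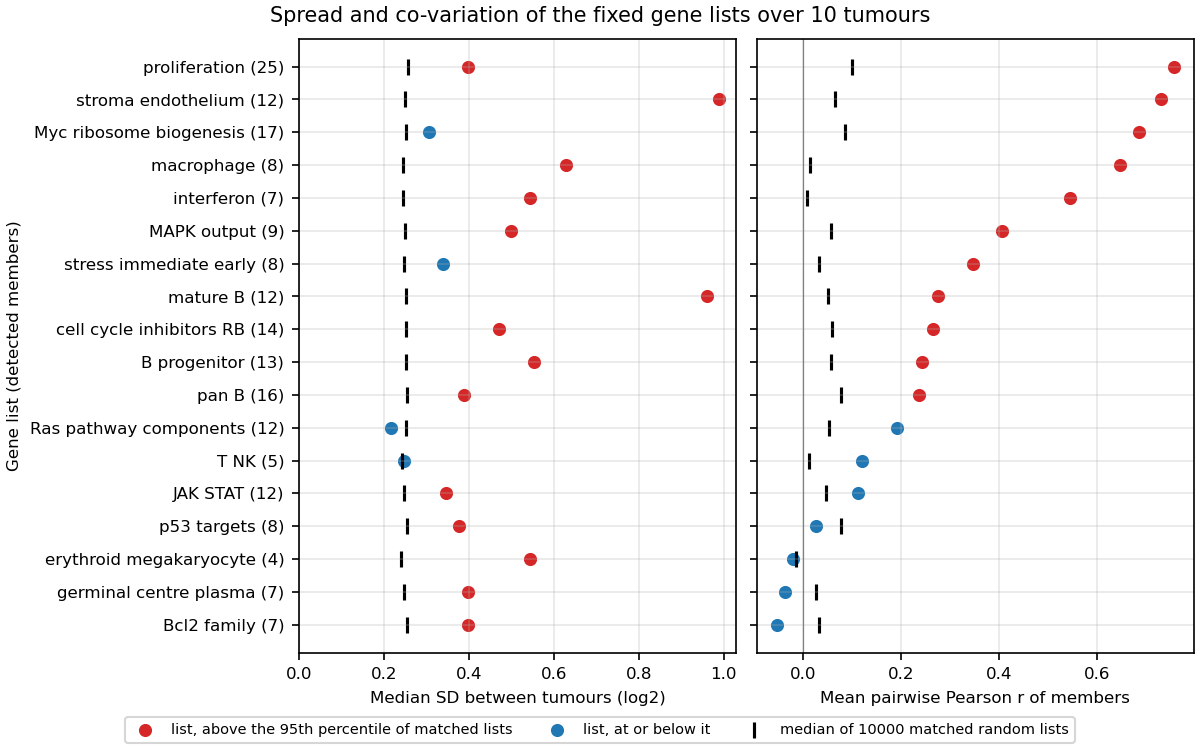
Median SD between tumours (left, log2 units) and mean pairwise Pearson correlation (right) of the detected members of 18 gene lists (vertical axis, with member numbers in brackets), with black ticks at the median of 10000 matched random lists. Red points, 14 on the left and 11 on the right, lie above the 95th percentile of those lists.

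Whether these programmes moved with each other across tumours was asked for 11 pairs of measures, and none passed Benjamini-Hochberg adjustment over the 11. The closest was proliferation with Myc and ribosome biogenesis (Pearson r = 0.758, permutation p = 0.0127, adjusted p = 0.140, Spearman rho = 0.758, permutation p = 0.0158, adjusted p = 0.174, n = 10), with r = 0.734 without the 2 tumours farthest from the median proliferation score. Of 1000 pairs of matched random lists, 79.8% had a lower r than this pair. MAPK output and mature B genes had r = 0.549 (permutation p = 0.101, adjusted p = 0.455, rho = 0.527, permutation p = 0.123, r = 0.293 without 2 tumours). MAPK output and proliferation had r = -0.518 (permutation p = 0.125, adjusted p = 0.455, rho = -0.479, permutation p = 0.165, r = -0.220 without 2 tumours), and 1.20% of random pairs had a lower r. Leaving out tumour 4 brought both pairs with proliferation past the threshold, to r = 0.824 with Myc and ribosome biogenesis and r = -0.842 with MAPK output (adjusted permutation p = 0.0326 for both). B progenitor and mature B genes had r = -0.00148 (permutation p = 0.997, rho = 0.00606, permutation p = 1, r = 0.124 without 2 tumours). For proliferation with B progenitor genes r was 0.474 (permutation p = 0.165, rho = 0.442, permutation p = 0.205, r = 0.261 without 2 tumours), and with mature B genes 0.0466 (permutation p = 0.895, rho = 0.0424, permutation p = 0.918, r = -0.173 without 2 tumours). The Cdkn2a level, below detection in every tumour, had r = 0.156 with p53 targets (permutation p = 0.673, rho = 0.103, permutation p = 0.787, r = -0.304 without 2 tumours) and r = -0.204 with proliferation (permutation p = 0.580, rho = -0.370, permutation p = 0.297, r = -0.645 without 2 tumours, r = 0.0285 without tumour 8). T and NK genes had r = -0.378 with macrophage genes (permutation p = 0.293, rho = -0.333, permutation p = 0.345, r = -0.416 without 2 tumours, r = 0.0796 without tumour 9) and r = 0.409 with mature B genes (permutation p = 0.241, rho = 0.552, permutation p = 0.105, r = 0.359 without 2 tumours). Interferon and macrophage genes had r = -0.0589 (permutation p = 0.878, rho = 0.212, permutation p = 0.558, r = -0.240 without 2 tumours). Adjusted permutation p-values of these other pairs ran from 0.455 to 0.997 for Pearson r, and none was below 0.450 for Spearman rho. All tests were two-sided, and a pair of the Kras level with MAPK output could not be computed.

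Which single genes varied with a programme was asked next. The chemokine receptor gene Ccr1 was higher in tumours with a higher MAPK output score, by 3.27 ± 0.62 log2 per unit of score (slope ± SE, limma adjusted p = 0.0265, n = 10), Cdh17, a cadherin gene, by 3.24 ± 0.62, the decoy receptor gene Il1r2 by 2.63 ± 0.41, Cyp4f18 by 2.63 ± 0.33 and S100a4 by 2.53 ± 0.46. Lower with the score were Cnksr3 (-1.90 ± 0.36, adjusted p = 0.0238), the pseudokinase gene Trib2 (-1.83 ± 0.38), Cd24a (-1.59 ± 0.35), Otub2 (-1.54 ± 0.16) and Niban3 (-1.47 ± 0.26). With members of the list itself left out, 146 of 7315 genes passed an adjusted p of 0.05, 93 with positive and 53 with negative slopes. Among the fixed lists, the immediate-early genes Junb and Ier2 and the mature B gene Cd37 had positive slopes and the pan-B gene Cd24a and the ribosome biogenesis gene Bop1 negative ones over all genes. Adjusted over the list alone, 3 stress, 1 mature B, 1 Ras component, 1 T and NK and 1 interferon gene had positive slopes, and 3 pan-B, 1 mature B and 1 Myc and ribosome biogenesis gene negative ones. In the remaining lists no member passed by either count.

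This set of genes depended on a few tumours. Without tumour 1 only 10 genes passed, all among the 146, without tumour 10 only 14, without tumour 2 only 50, and without the 2 tumours farthest from the median score 0 by limma. The count was 94 when the probe sets of a gene were averaged and 56 with no detection filter. Genes with negative slopes, 53 in the main fit, numbered 2 without tumour 1, 2 without tumour 10 and 92 without tumour 4.

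The genes with negative slopes were unevenly spread over the chromosomes, which was seen only after the fit. The autosome that carries Myc, Il7r and Bop1 held 33 of the 53 genes (62.3%) and 0 of the 93 with positive slopes, against 314 of the 7315 tested genes (4.29%), and no other autosome held more than 4 of the 53. Neighbouring genes are not independent, so no test is given for this count. The median deviation of all detected genes on that autosome, relative to those on the other autosomes, ran from -0.23 in tumour 1 to 0.38 in tumour 4. Of the 19 autosomes, 3 others also differed widely between tumours. The autosome of Blk and Rb1 was highest in tumours 6 (0.30) and 5 (0.28) and lowest in tumour 4 (-0.18), that of Igll1, Vpreb1 and Erg was highest in tumour 2 (0.32), and that of Braf, Cdkn1b and Ccnd2 in tumour 7 (0.20). The range between tumours was 0.61, 0.48, 0.44 and 0.25 for these 4 autosomes and at most 0.12 for the other 15.

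**Figure D5:**
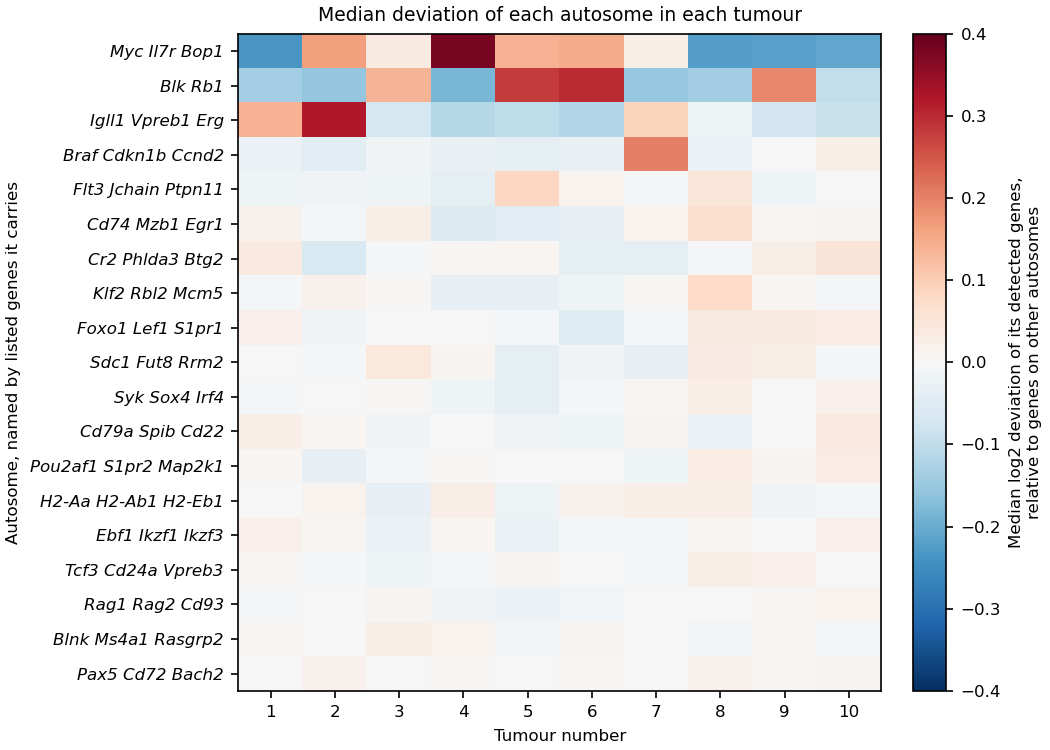
Heat map of the median log2 deviation of the detected genes on each of 19 autosomes (vertical axis, each named by listed genes it carries) relative to genes on the other autosomes, in tumours 1 to 10 (horizontal axis). The autosome of Myc was highest in tumour 4 (0.38), that of Blk and Rb1 in tumour 6 (0.30), that of Igll1 in tumour 2 (0.32) and that of Braf in tumour 7 (0.20).

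Fgf13, which encodes an intracellular fibroblast growth factor homologue, was higher in tumours with a higher proliferation score, by 2.65 ± 0.28 log2 per unit of score (slope ± SE, limma adjusted p = 0.000946, n = 10), the E2F family genes E2f7 and E2f2 by 2.04 ± 0.27 and 1.81 ± 0.31, Uchl1 by 1.97 ± 0.54 and Chaf1b, a subunit of the chromatin assembly factor that acts at replication, by 1.70 ± 0.43. Cilp (-2.71 ± 0.75), the interferon-induced Ifi209 (-2.62 ± 0.46), Alox5ap (-2.36 ± 0.48), Cd9 (-2.22 ± 0.58) and Sema4a (-2.05 ± 0.46) were lower. In all, 858 of 7299 genes passed, 802 with positive and 56 with negative slopes. From the fixed lists these included Cdkn2c, Rbl1 and E2f2 (3 of 14 cell cycle inhibitor and RB genes), Nop56, Pa2g4 and Odc1 (3 of 17 Myc and ribosome biogenesis genes) and Sox4 with positive slopes, and Xbp1 with a negative one. Adjusted over the list alone, 6 Myc, 5 cell cycle inhibitor and 1 B progenitor gene had positive slopes and 5 of 7 interferon, 1 cell cycle inhibitor and 1 plasma cell gene negative ones, with 0 in the remaining lists by either count.

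The size of this set varied with tumours and scaling. It was 157 without tumour 8, 568 without tumour 10, and 131 without the 2 tumours farthest from the median score. Without tumours 4 and 7, which had the highest levels of salivary transcripts, it was 541, and with other-cell content as a covariate 539. Quantile normalization of the deposited values gave 392 genes (322 with positive and 70 with negative slopes), and centring each array on its median gave 1338 (1302 and 36). Genes with negative slopes numbered 138 without tumour 4, 20 without tumour 1 and 15 without tumour 8.

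No gene passed the threshold for the level of Cdkn2a or for the mature B score. For Cdkn2a, which reached the detection level in no tumour, limma found 0 of 7324 genes over all genes and 264 at an unadjusted p under 0.05. The 264 are a smaller share of the genes than the 0.05 that unrelated genes would give on average. Adjusted over the list alone, 6 of 8 macrophage genes had negative slopes, and tumour 9 had both the highest Cdkn2a value (5.49) and the lowest macrophage score (-1.55). For the mature B score limma found 0 of 7312 genes and 694 at an unadjusted p under 0.05. The 694 are a larger share than 0.05, but a random ordering of this score gave up to 346 genes past the adjusted threshold. Adjusted over the list alone, 4 of 8 macrophage, 3 of 12 stromal and 1 of 7 Bcl2 family genes had negative slopes, and tumour 9, with the highest mature B score (0.94), also had the lowest stromal score (-2.23). Leaving out tumour 1, 2 or 8 in turn gave 1 gene for the mature B score.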

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

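The T and NK cell test in tumour 9, both tests of scaling by rank (which replaced tests of the arrays' medians, void because RMA equalises these) and the bounds for both comparisons with random orderings, and the removal of scores from the MAPK output list, were chosen only after results were seen, and the second gene lists were written after the patterns were noticed but before their own levels were examined. Single tumours that stood far from the other 9 were picked out in 12 of 134 sets of values, where chance gives about 1 in 20, or 6.70. Many of these sets were genes named for a large SD or for their slope, so 12 against 6.70 does not test for an excess.

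Scgb1b27 stood at 14.64 in tumour 4, with 8.98 as the next value, and 12 of 12 genes of secreted salivary proteins, a list drawn up from the pattern itself and so no test of it, had tumours 4 and 7 as their highest, for example Amy1 (12.47 and 13.05), Car6 (13.77 and 12.90) and Smr3a (12.25 and 13.04), each at most 5.07 in the others. A scaling difference of the arrays, which would keep the order of genes within an array, is argued against by the median rank of these 12 genes, at the 99.4 percentile of all genes in tumour 4 and 99.7 in tumour 7 against 15.1 to 29.4 in the others. Salivary gland epithelium in the tissue is a candidate source that stays open. Of 19 measured genes of a second list, of epithelial genes, only 3 were detected on average, which limits the test. Tumours 4 and 7 were the highest for 5 of the 19 (chance p = 4.86e-05 if genes were independent). That is fewer than the 10 the explanation called for but more than the 2 set as its lower bound. Tumour 4 was the highest for 16, such as Krt18 (8.85, and 6.84 in tumour 7). No biological explanation was tested, since all tumours share 1 group.

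Tumour 9 had the lowest stromal score (-2.23, next -0.58) and macrophage score (-1.55, next -0.33), with Fabp4 at 3.73 (next 7.33), C1qc at 4.65 (next 7.49) and Cd68 at 6.93 (next 7.89). A lower share of every other cell type is argued against by the T and NK cell genes, of which 10 of 20 were highest in tumour 9 and 1 lowest. Among them Cd3e stood at 7.65 (next 7.21) and Cd3g at 7.50 (at most 4.63 elsewhere). Only 5 of the 20 were detected on average, and whether tumour cells express any of them was not tested, which limits this argument. A lower share of stromal cells and macrophages met its test, as 17 of 19 measured genes of a second stromal and macrophage list were lowest in tumour 9, among them Serping1 (4.66, next 7.33) and Col4a2 (4.50, next 7.02). A scaling difference is argued against by rank, as the median of the 20 detected stromal and macrophage genes stood at the 52.7 percentile of all genes in tumour 9 and at 78.1 to 91.9 in the others. The low values may reflect how the tissue was taken or the tumour itself, which the labels do not separate, and no biological explanation was tested.

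MAPK output genes moved together (mean r = 0.406), and simple causes were set against this. The stress and immediate-early score had the highest r with MAPK output of the scores removed (0.805), so stress may account for part of the shared movement. After that score was removed from every gene, the list stayed at the 97.01 percentile of matched lists (mean r = 0.318). It stood at 99.68 (0.407) with the mean other-cell score removed, which had little to remove (r = 0.140 with MAPK output). With the T and NK score removed (r = 0.633) it stood at 99.91 (0.473). It stood at 99.47 (0.424) with a score of 6 granulocyte genes removed (r = 0.586) and at 98.91 (0.369) without tumour 1. Each of these alone, as far as the scores measure it, is unlikely to be the whole cause. Tumour 10, the array most like tumour 1 (r = 0.957), stayed in when tumour 1 was left out. Tumours 1 and 10 together were therefore not tested as a cause. Of 100 random orderings of the score, 0 gave as many as 146 associated genes (highest 28), which makes chance ordering an unlikely cause. The score was made from the same arrays, so the orderings cannot tell a MAPK programme from another axis of variation shared by many genes. The first principal component of the detected genes (26.4% of the variance) weighted tumours 1 (0.57) and 10 (0.47) opposite to 8 (-0.39) and 2 (-0.35). Tumours 1 and 10 also had the highest MAPK output scores and tumour 2 the lowest. A random ordering of the mature B score gave up to 346 genes, so orderings of these tumours can give large counts. The comparison does not address a dependence on tumours 1 and 10, without which 10 and 14 genes passed. No biological explanation was tested, because no group differs in Kras genotype.

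For the proliferation score 0 of 100 random orderings gave as many as 858 genes (highest 3), so chance ordering is an unlikely cause. Random orderings cannot address a shift of whole arrays, nor another axis of variation that the score shares with many genes of the same arrays. Tumours 4 and 8, with the lowest and highest score, also had the lowest and highest median deviation over all detected genes (-0.146 and 0.123). After quantile normalization 392 genes passed.

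Cdkn2b stood at 6.50 in tumour 1, with 4.83 as the next value. Cd24a stood at 8.79 in tumour 1, with 11.11 as the next lowest. Aen stood at 8.47 in tumour 8 (next 8.09). The cell cycle inhibitor and RB pathway score was 0.56 in tumour 8 (next 0.05). Oas2 stood at 7.76 in tumour 4 (next 6.83).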

How the results depend on the processing

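Leaving out tumours 4 and 7 and setting the detection level on the highest tumour were alternatives chosen only after the data were seen; the others were planned. Under all alternatives run, the Cdkn2a fit gave 0 genes by limma (264 at an unadjusted p under 0.05 with the planned settings), and MAPK output with mature B genes, proliferation with B progenitor genes and T and NK with mature B genes kept their direction without passing the threshold. The numbers of detected genes and of lists above matched genes stayed within 1.5 times. For the results below the cause was not tested, except that settings without tumours fit fewer samples. Genes with an SD above 1 numbered 103 with probe sets averaged, 295 with no filter and 288 with detection on the highest tumour. Genes associated with MAPK output numbered 94 with probe sets averaged, 56 with no filter, 0 without the 2 farthest tumours and 10 to 194 with 1 tumour left out (10 without tumour 1, 14 without tumour 10, 50 without tumour 2). Genes associated with proliferation numbered 1338 with arrays centred (838 of the 858 shared), 392 with quantile normalization (366 shared), 539 with other cells removed, 131 without the 2 farthest tumours (87 shared), 541 without tumours 4 and 7, and 157 to 866 with 1 tumour left out (157 without tumour 8, 144 shared, and 568 without tumour 10). Genes associated with mature B numbered 1 at the 75th percentile level, with no filter, with other cells removed and with detection on the highest tumour, and 0 to 1 with 1 tumour left out.

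With 1 tumour left out, r for MAPK output with proliferation ran from -0.842 (without tumour 4, adjusted permutation p = 0.0326) to -0.358 (without tumour 1), and for proliferation with Myc and ribosome biogenesis from 0.645 (without tumour 8) to 0.824 (without tumour 4, adjusted permutation p = 0.0326). The 6 pairs below changed sign under some alternative without passing the threshold. B progenitor with mature B (r = -0.00148) gave 0.0739 with probe sets averaged, 0.0895 without probe sets that may cross-hybridise, 0.0586 with arrays centred, and -0.397 to 0.161 with 1 tumour left out. Proliferation with mature B (0.0466) gave -0.102 with quantile normalization, -0.0872 at the 75th percentile, -0.116 with no filter, -0.139 with other cells removed, -0.463 without tumours 4 and 7, -0.0959 with detection on the highest tumour, and -0.399 to 0.274 with 1 tumour left out. Interferon with macrophage (-0.0589) gave 0.0200 without cross-hybridising probe sets, 0.0268 with quantile normalization, 0.109 at the 75th percentile, 0.124 with no filter, 0.105 with detection on the highest tumour, and -0.313 to 0.5003 with 1 tumour left out. Cdkn2a with p53 targets (0.156) gave -0.0754 with other cells removed and -0.0254 to 0.571 with 1 tumour left out. With 1 tumour left out, Cdkn2a with proliferation (-0.204) ran from -0.455 to 0.0285 (without tumour 8), and T and NK with macrophage (-0.378) from -0.487 to 0.0796 (without tumour 9), the only alternative in each that changed the sign.

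Of single levels, 1646 values stayed within 1 SD and 52 moved further. List spreads fell to or below the 95th percentile in 28 cases and rose above it in 13, and list correlations in 13 and 9. Correlation was lost under at least 1 alternative by the pan-B, B progenitor, mature B, cell cycle inhibitor and stress lists, leaving 8 lists with arrays centred and 9 without probe sets that may cross-hybridise. Spread was lost by the germinal centre and plasma cell, p53 target, Bcl2 family, erythroid and JAK-STAT lists, leaving 10 with the scaled median absolute deviation. Slopes of named genes lost the threshold in 55 cases for MAPK output and 47 for proliferation, and none changed sign. The pair with the Kras level was not run under any setting. Signal over background limits genes below the detection level, such as Cdkn2a and Cdkn2b, which reached it in no tumour and whose differences may be mostly background (the Cdkn2a fit gave 0 genes without any filter too).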

Other observations

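All tests in this part, of JAK-STAT feedback genes and of chromosomes, were chosen only after the pattern they follow was seen, and the genes named were chosen after their values were seen. Tumours differed in markers of the stage of B cell development. Dntt, which encodes the enzyme that adds nucleotides at immunoglobulin joints, stood at 9.90 in tumour 7, 9.36 in tumour 5 and 6.96 in tumour 6, and at most 5.23 in the others. The stem cell factor receptor gene Kit stood at 8.32 in tumour 5 and 8.02 in tumour 6, and at most 6.65 elsewhere. Ighm, the constant region of IgM, was present throughout (13.15 ± 0.47, n = 10), and of 16 measured immunoglobulin variable genes 4 were detected. Iglv1, a lambda light chain gene, reached 12.05 in tumour 4 and at most 7.79 elsewhere, and Igkv15-103, a kappa gene, 9.72 in tumour 3 and at most 6.02 elsewhere. Probe sets of immunoglobulin segments can share sequence with related segments, so these values are uncertain as to the segment. Neither segment is read here as a marker of stage. Whether their transcripts came from tumour cells or other cells was not tested, and tumour 4 also had the highest Igha value (10.26).

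Further genes were high in a few tumours. Cdh1, which encodes E-cadherin, stood at 8.88 in tumour 9, 8.30 in tumour 1 and 7.75 in tumour 10, and at most 5.72 in the others. The granulocyte genes S100a8 and S100a9 stood at 8.92 and 8.49 in tumour 1, 8.23 and 7.94 in tumour 9 and 8.02 and 7.56 in tumour 8, and at most 6.65 and 5.89 elsewhere. The NK cell receptor gene Klrd1 stood at 8.97 in tumour 1, 7.69 in tumour 9 and 7.55 in tumour 3. Xist, expressed from the inactive X chromosome, ran from 12.08 to 12.68 in tumours 1, 5, 6, 8 and 9 and from 6.08 to 6.90 in the others, where the Y-linked Eif2s3y ran from 6.57 to 6.67 against at most 2.97 in the first set. Tumours 4 and 7, with the highest levels of salivary transcripts, were both of the Y-positive set. They also had the highest values of Igha, the constant region of IgA (10.26 and 9.05), followed by 8.87 in tumour 8 and 8.81 in tumour 9, and whether Igha came from tumour cells or other cells was not tested.

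Socs2, Cish and Pim1, which are induced by STAT5 downstream of cytokine receptors, varied together over the 10 tumours, with r = 0.915 for Socs2 with Pim1 (permutation p = 8e-05, adjusted p = 0.00032 over 4 pairs, rho = 0.927, permutation p = 0.00036, r = 0.852 without 2 tumours), 0.841 for Cish with Pim1 (permutation p = 0.00176, adjusted p = 0.00331, rho = 0.903, permutation p = 0.00096, r = 0.740 without 2 tumours) and 0.820 for Socs2 with Cish (permutation p = 0.00248, adjusted p = 0.00331, rho = 0.903, permutation p = 0.00079, r = 0.819 without 2 tumours). The trio was picked for moving together, so these values describe it and do not test it. A hypothesis is that the interleukin-7 receptor sets their level, since Il7r ran from 9.41 in tumour 1 to 11.75 in tumour 6. The mean of the trio had r = 0.554 with Il7r (permutation p = 0.0969, adjusted p = 0.0969, rho = 0.539, permutation p = 0.113, r = 0.454 without 2 tumours), which leaves the hypothesis open, as the test could neither bear it out nor exclude it.

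Of the genes lower with the MAPK output score, 33 of 53 lie on the autosome that carries Myc, and a hypothesis is that tumours differ in copy number of that chromosome. On its 281 detected genes that did not pass in that fit, the median deviation ranged over 0.608 between tumours, against 0.478 on the next autosome and a median of 0.0714 on the others. The other part of the test, r = -0.511 with the MAPK output score (permutation p = 0.132, rho = -0.333, permutation p = 0.346, r = -0.272 without 2 tumours), decides nothing, since genes were left out for passing in the fit on that score, which draws r towards 0. Over all 314 detected genes r was -0.619 (permutation p = 0.0583, rho = -0.624, permutation p = 0.0609, r = -0.378 without 2 tumours), a value that includes the genes in which the pattern was seen. A link between this chromosome and MAPK output therefore stays open. The deviation of the 281 genes had r = 0.0708 with the level of Myc itself (permutation p = 0.852, rho = -0.127, permutation p = 0.733).

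Across all autosomes 4 stood apart, a number chosen after their ranges were seen, and a hypothesis is that they differ in copy number as a whole in some tumours. If so, the genes on either side of the middle gene of each should move alike, and the r between these sides over tumours was 0.998 for the autosome of Myc, 0.982 for that of Blk and Rb1, 0.967 for that of Igll1 and Erg, and 0.881 for that of Braf and Ccnd2, against -0.303 to 0.752 on the other 15. The ranges of 0.61 to 0.25 may be set beside 0.585, the log2 ratio of 3 to 2 copies with no dilution by normal cells. These values are consistent with gains or losses of whole chromosomes, but DNA was not measured here, and the sides were compared on the data that showed the pattern.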
